A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

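The series holds 17 samples of budding yeast (Saccharomyces cerevisiae) of the strain BY4741, a laboratory strain of mating type a with deletions in his3, leu2, met15 and ura3. Cells were grown in rich medium (YPD) to an optical density of 0.8, per the labels' protocols. Values were at hand for 5 samples, all from SMORE-seq of wild-type cells, a method that ligates an adapter to RNA 5′ ends and so records where transcripts begin. The other 12 samples, from chromatin immunoprecipitation and MNase digestion, were not analysed here. TAP (tobacco acid pyrophosphatase) opens the 5′ cap and leaves a phosphate that can be ligated. CIP (calf intestinal phosphatase), used before TAP, removes 5′ phosphates from uncapped RNA, so that these ends are not ligated.

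The deposited tables hold whole-number counts per gene identifier with no normalization, per the file headers and the values. The submitters' processing notes list bcl2fastq, BWA 0.6.2, bedtools and featureCounts and the genome build sacCer3, with no role or order. The counted feature and the strand setting are not given in the sources used here. The 3 ribo depletion samples shared 1 table of counts, and how the authors combined them is not given in the sources used here. The poly(A)-selected TAP and CIP/TAP groups had 1 library each. With no replicate values in any group, no comparison had a replicate check, no test between groups was run and no p-value is given.

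The 3 tables listed the same 5797 identifiers. The total was 2821480 counts for ribo depletion, 864536 for TAP and 1097457 for CIP/TAP. A count of 0 allows up to 3 counts, which is 1.06 CPM (counts scaled to an equal total) in the ribo depletion table, 3.47 in TAP and 2.73 in CIP/TAP. Of the identifiers, 5794 matched the gene table of the R64 assembly, the assembly that sacCer3 names, and the 3 others were at 0 in every table. Positions and neighbours came from that gene table, and strand came from the W or C of the systematic names. The gene table gave no exons, so intron-containing genes and Ty elements, which were planned as lists, were not run.

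The position of each identifier's upstream neighbour was compared with its count. The nearest annotated gene beyond the 5′ end was called divergent when it lay on the opposite strand and was transcribed away, and tandem when it lay on the same strand. The share of identifiers with at least 10 counts was given with an exact Clopper-Pearson 95% interval. These values, in the report, put most counts on identifiers with a close divergent neighbour. An identifier's count is therefore not described as the expression of that gene, and overlapping or antisense transcripts were not told apart. Groups of identifiers by the class of the divergent neighbour within 500 bp were formed after the values had been seen.

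For each pair of tables, counts were scaled with edgeR 4.0.16 (TMM factors of the pair, in R 4.3.3), and the ratio was log2 of (count + 0.5) over the scaled library size. Identifiers with at least 50 counts over both tables were measured, and a ratio of at least 2-fold was counted as higher or lower. Each ratio has an exact 95% interval conditional on the summed count (Clopper-Pearson), from scipy 1.17.1 in Python 3.11.15. Reads had no molecular identifiers, so intervals and floors cover counting error only. A ratio against a count of 0 was given as a lower bound from the floor of 3 counts per table. Medians of gene lists carry an order-statistic 95% interval, given from 6 measured members on since fewer cannot reach that level, and a percentile among 10000 random lists of the same size matched on mean count in 20 bins, which describes these libraries alone.

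The lists were fixed before the data were examined. They covered cytosolic ribosomal proteins, ribosome biogenesis, translation factors, the proteasome, glycolysis and fermentation, the TCA cycle, the nuclear-encoded respiratory chain, ergosterol synthesis, cell wall and membrane genes, core histones, H2A.Z and its remodellers, stress and heat shock, glucose-repressed genes, cyclins and other short-lived transcripts, substrates of nonsense-mediated decay, the strain's deleted genes, genes of both mating types, and noncoding, mitochondrial, tRNA, snoRNA and snRNA genes. The genes named in the text were also set by a rule fixed at that time. The rule took the 12 highest and 12 lowest ratios of CIP/TAP over TAP with at least 200 counts, and the 12 largest in each direction for both poly(A) libraries against ribo depletion. It added the 10 highest counts of each table, HTZ1, SWR1, INO80, strain and mating type genes, the extreme members of each list, and the 3 closest and 3 most unequal divergent pairs.

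On Poisson counts simulated from the tables with 200 changed genes, every measured 4-fold and 8-fold change passed the 2-fold rule in each comparison. Among unchanged genes, 0.209% of 1435 passed it for CIP/TAP against TAP, 0.586% of 1707 for TAP against ribo depletion and 0.182% of 1646 for CIP/TAP against ribo depletion. The simulations held counting error only, with no variation between libraries, so these rates cannot stand for those between replicate libraries. Alternatives were total counts, DESeq2 1.42.0 size factors, upper-quartile scaling, filters of 10 and 200 counts and none, 5 added to each count, protein-coding nuclear genes only, the deeper table thinned to equal totals, and an exact interval wholly beyond 2-fold. Alternatives chosen after seeing the data were leaving out the DSC3 identifier, keeping only identifiers with a divergent neighbour within 500 bp, and a neighbour distance of 150 to 350 bp.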

Results

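RNA 5′ ends of wild-type BY4741 yeast were counted by SMORE-seq after ribosomal RNA depletion (3 samples in 1 table) or poly(A) selection with TAP (1 library) or CIP and TAP (1 library). The series design names these libraries as a map of transcripts across the genome. The tables held 2821480, 864536 and 1097457 counts over 5797 gene identifiers. Counts were concentrated on few identifiers. DSC3 alone held 17.3% of the ribo depletion counts, and UTR5 held 14.1% of TAP and 12.2% of CIP/TAP. No counts were listed for 58.5%, 52.7% and 55.6% of the identifiers in ribo depletion, TAP and CIP/TAP, and 2296 identifiers were at 0 in all 3 tables.

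Genes for cytosolic ribosomal proteins were mostly without counts under their own identifiers. Of 138 such genes, 10 had at least 10 counts in TAP (7.25%, exact 95% interval 3.53 to 12.9%), 12 in ribo depletion and 16 in CIP/TAP, and 96 were at 0 in all 3 tables. Over all identifiers the shares with at least 10 counts were 37.1% in TAP, 31.5% in ribo depletion and 33.0% in CIP/TAP. Of 21 glycolysis and fermentation genes, 5 (23.8%, 8.22 to 47.2%), 6 and 3 had at least 10 counts in the same order, shares whose intervals include those over all identifiers. The translation factor HYP2 (eIF5A) had 0, 0 and 1 counts in ribo depletion, TAP and CIP/TAP, while UTR5 (YEL035C, R64 chromosome V, 85045 to 85545), which starts 130 bp away and is transcribed the other way, had 100770, 121682 and 133472. The enolase gene ENO2 had 0, 38 and 26 counts, while its divergent neighbour YHR173C (chromosome VIII, 450815 to 451153) had 96800, 30242 and 31969. DSC3 (YOR223W, chromosome XV, 759782 to 760660), with 488331, 1121 and 1162 counts, started 252 bp from SNR35, a small nucleolar RNA gene on the opposite strand. YER137C (chromosome V, 441373 to 441819), with 47473, 4094 and 116 counts, started 167 bp from SCR1, the RNA of the signal recognition particle.

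**Figure D1:**
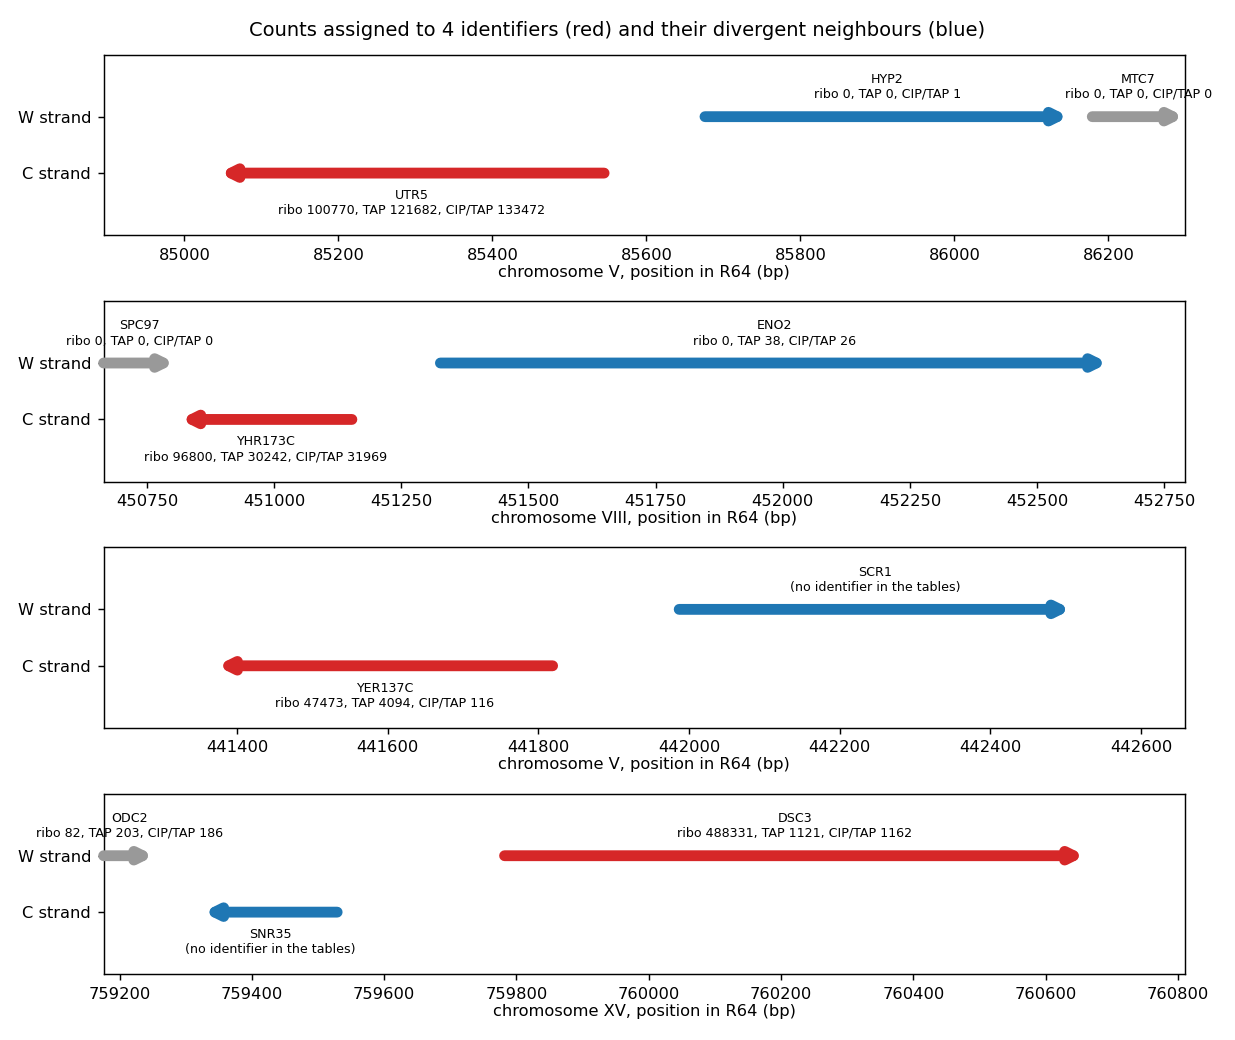
Maps of 4 identifiers (red) and their divergent neighbours (blue), with position in bp on the R64 assembly on the x axis, the strand on the y axis, and the counts in the 3 tables beside each gene that has an identifier. UTR5 and YHR173C hold 121682 and 30242 TAP counts, while HYP2 and ENO2 hold 0 and 38.

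The orientation of the upstream neighbour separated identifiers with counts from those without. With a divergent neighbour 150 to 350 bp away (973 identifiers), at least 10 counts were found for 82.4% in ribo depletion (exact 95% interval 79.9 to 84.8%), 87.4% in TAP (85.1 to 89.4%) and 84.5% in CIP/TAP (82.1 to 86.7%). With a tandem neighbour at the same distance (1095 identifiers), the shares were 17.5% (15.3 to 19.9%), 19.9% (17.6 to 22.4%) and 15.3% (13.3 to 17.6%). Identifiers with a divergent neighbour within 500 bp, 1478 in number, held 84.9%, 85.4% and 86.7% of all counts in ribo depletion, TAP and CIP/TAP. In TAP the share for divergent neighbours was 59.1% at 0 to 50 bp (22 identifiers), 60% at 51 to 100 bp (25), 58.1% at 101 to 150 bp (31), 91.4% at 151 to 200 bp, 70.1% at 351 to 400 bp and 32.5% at 501 to 600 bp. Shares by the downstream neighbour differed by less than counting error. With a tandem upstream neighbour, 22.2% of identifiers had at least 10 TAP counts when the downstream neighbour was convergent (20.1 to 24.5%) and 23.0% when it was tandem (20.8 to 25.3%).

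**Figure D2:**
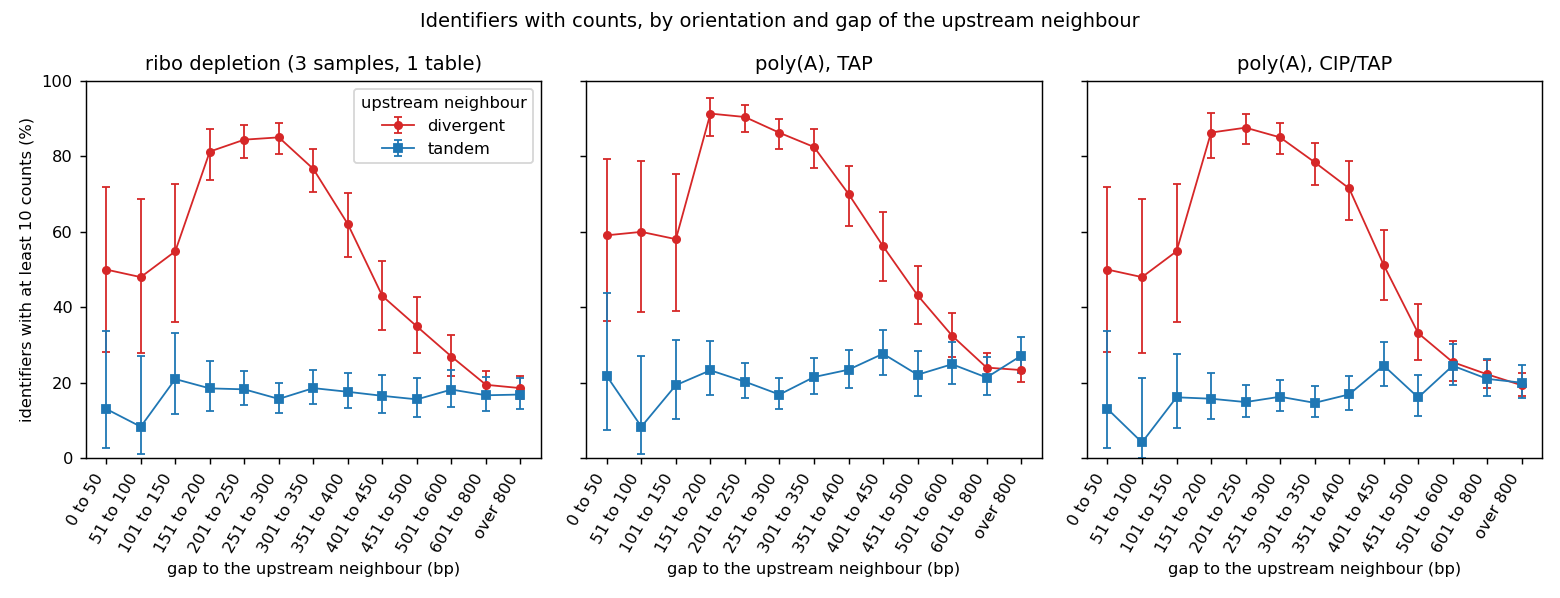
Share of identifiers with at least 10 counts (y axis, %) by gap to the upstream neighbour (x axis, bp) for divergent (red) and tandem (blue) neighbours in each table, with exact 95% intervals as bars. In TAP the divergent share was 91.4% at 151 to 200 bp and 23.4% above 800 bp.

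The genes that define the strain label and the design could not be read as transcripts for that reason. LEU2, URA3 and MET17, deleted in BY4741, were at 0 in all 3 tables. HIS3, in which the strain also has a deletion, had 655, 650 and 730 counts, with MRM1 divergent at 237 bp. The extent of the deletion was not considered, so 5′ ends from a remaining part of HIS3 are not excluded. Among genes of mating type a, MFA2, STE2, STE6, BAR1 and AGA2 were at 0 and MFA1 had 34, 1 and 28 counts. Among genes of mating type alpha, MF(ALPHA)1 and STE3 were at 0, MF(ALPHA)2 had 0, 3 and 28 counts and SAG1 had 427, 108 and 189. HTZ1, which encodes H2A.Z, had 0, 33 and 2 counts. SWR1 and INO80, the remodellers studied in the series, had 1494, 118 and 160 and 11, 4 and 9 counts.

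CIP/TAP against TAP asked which 5′ ends depend on uncapped phosphates. The lowest ratio among identifiers with at least 200 counts was that of YER137C beside SCR1, at log2 −5.32 (95% interval −5.60 to −5.06). Of 8 measured identifiers beside divergent tRNA genes within 500 bp, 7 were at least 2-fold lower and 1, PMT7, was higher (1.74, 0.85 to 2.84), with a median of −3.83 (−7.36 to 1.74, percentile 0.04 of random lists). All 24 identifiers of this class, measured or not, held 193 counts in CIP/TAP and 1353 in TAP. TGL2 had 14 counts against 386 (−4.92, −5.85 to −4.20), MIC19 beside SUP11 had 6 against 108 (−4.24, −5.83 to −3.18), and COQ6 had 26 against 249 (−3.42, −4.09 to −2.86). YJL028W beside EMT5, a methionine tRNA gene, had 0 against 72. Identifiers beside snoRNA and snRNA genes had a median of −0.13 (9 measured, −1.28 to 1.30), and the 1047 beside protein-coding genes had a median of 0.15 (0.09 to 0.21), which was −0.01 with total counts and −0.05 with upper-quartile scaling.

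Over all 1679 identifiers measured, 373 were at least 2-fold higher in CIP/TAP and 262 lower. Among identifiers with at least 200 counts, FIP1, a subunit of the polyadenylation factor, had the highest ratio, with 237 counts against 1 (7.12, 5.21 to 13.01). It was followed by YAP1802 (3.37, 2.71 to 4.18), YTA7 (3.35, 2.65 to 4.22), TAF7, a TFIID subunit (3.34, 2.64 to 4.21), and ESC1 (3.33, 2.74 to 4.04). DUG3, STB2, TRM82, ARC40, MUD2, DIA2 and DPB2 followed, down to 2.53. The 12 lowest with at least 200 counts held, besides YER137C, TGL2 and COQ6, VTC1 (−3.79, −4.67 to −3.10), TMN2, TRM1, YLR157W-E, KAP114, KEL1, FSH2, MND2 and MRPL28, the last at −1.85 (−2.25 to −1.48). With 1 library on each side there was no replicate check, and calls among identifiers under 200 counts rest on few counts. Total counts moved the median of all identifiers by −0.16 and the higher share of the calls from 58.7% to 51.9%, and upper-quartile scaling moved the median by −0.20 and turned the balance to 304 higher and 311 lower (49.4%). A filter of 10 counts turned it as well, to 622 higher and 783 lower.

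**Figure D3:**
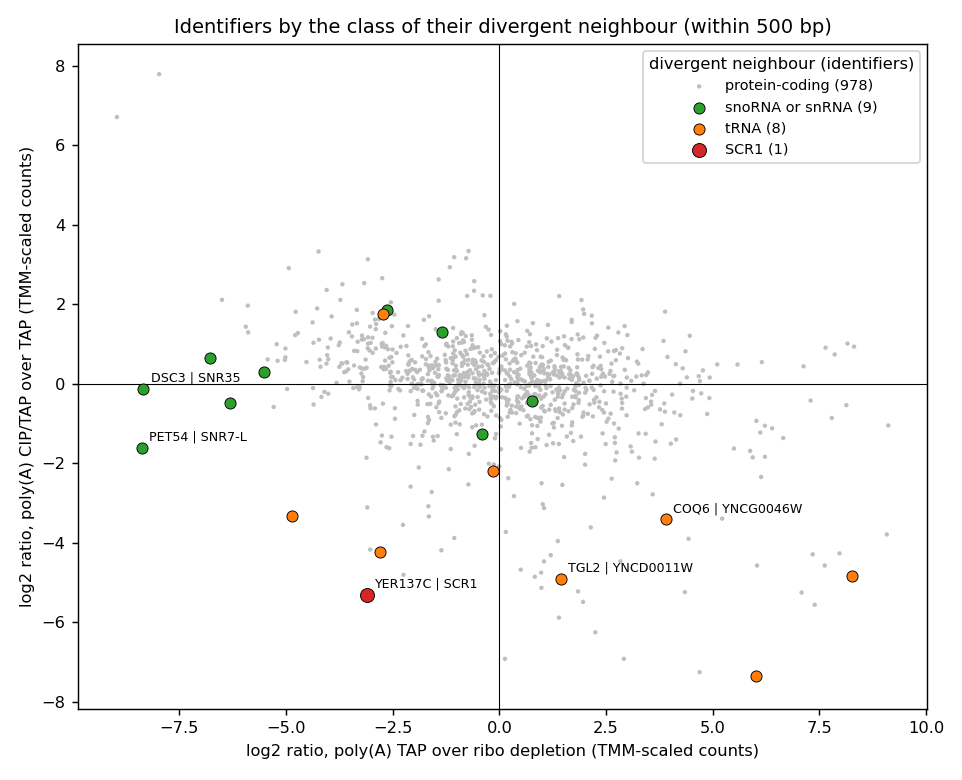
Log2 ratio of TAP over ribo depletion (x axis) and of CIP/TAP over TAP (y axis), TMM-scaled, for identifiers with a divergent neighbour within 500 bp and at least 50 counts in both comparisons, coloured by the class of the neighbour, with the TAP table entering both axes. The identifier beside SCR1 lies at −3.11 and −5.32, and DSC3 beside SNR35 at −8.34 and −0.13.

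Poly(A) TAP against ribo depletion asked which 5′ ends differ between RNA selected by its tail and RNA freed of ribosomal RNA. The titles of the ribo depletion samples name no TAP or CIP treatment. A difference in enzyme treatment is therefore not told apart from selection in either comparison with ribo depletion. Identifiers beside divergent snoRNA and snRNA genes were lower after poly(A) selection. They held 19.1% of the ribo depletion counts, 17.3% in DSC3 alone, and 0.296% of the TAP counts. Of these identifiers, 9 of 12 measured were at least 2-fold lower and 0 higher, with a median of −4.84 (−8.34 to −0.41, percentile 0 of random lists). DSC3 beside SNR35 was at −8.34 (−8.43 to −8.26), PET54 beside SNR7-L, the U5 spliceosomal RNA, at −8.38 (−8.82 to −8.01), FSF1 beside SNR8 at −6.79 (−7.16 to −6.46), AAR2 beside SNR56 at −6.31 (−6.70 to −5.97) and TFA2 beside SNR42 at −5.52 (−5.78 to −5.28). YOL097W-A beside SNR58, with 228 counts against 179, was at 0.77 (0.48 to 1.06). YER137C beside SCR1 was at −3.11 (−3.16 to −3.07). The 11 measured identifiers beside tRNA genes went both ways, with 4 higher and 5 lower, and their median of −0.15 was above 0 with total counts (1.13) and upper-quartile scaling (0.21).

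Over all 1646 identifiers measured, 525 were at least 2-fold higher in TAP and 626 lower. YDR524W-C had 1032 counts in TAP and 2 in ribo depletion (9.11, 7.58 to 12.48). SLM5, CLP1, NFT1, SNX41 and NIP100 had 139, 130, 180, 118 and 106 TAP counts and 0 in ribo depletion, at least 62.1-fold, 58.0-fold, 80.4-fold, 52.7-fold and 47.3-fold higher. SUR1, PLN1, VCX1, UBX7, SLD2 and YJR154W were also at 0 in ribo depletion, and the bound for YJR154W was at least 37.5-fold. In the other direction TCM62, a mitochondrial chaperone gene, had 5146 counts in ribo depletion and 0 in TAP, at least 1281-fold lower. PDR16, MRP49, IRA2 and FEX1 had 1275, 1011, 781 and 777 counts in ribo depletion and 0 in TAP, at least 317.3-fold, 251.6-fold, 194.3-fold and 193.4-fold lower. UPA2, PCT1, TRS120, RHO4, YAT1, RPL33A and AIM24 were also at 0 in TAP, and the bound for AIM24 was at least 68.7-fold. RRT15 had 10311 TAP counts against 983 (3.81, 3.72 to 3.91). The direction of the balance depended on scaling and filter, since total counts moved the median of all identifiers by 1.28 and the higher share of the calls from 45.6% to 69.0%. Upper-quartile scaling moved that median by 0.37 and DESeq2 size factors by −0.13, and a filter of 10 counts gave 1100 higher and 859 lower.

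Poly(A) CIP/TAP against ribo depletion was low for the same classes of small RNA neighbours and for most tRNA neighbours measured here. Identifiers beside snoRNA and snRNA genes had a median of −5.34 (−8.41 to −0.71), with 9 of 12 lower and 0 higher, and DSC3 was at −8.41 (−8.49 to −8.32). Identifiers beside tRNA genes had a median of −6.85 (−8.96 to −0.92), with 6 of 7 lower, and YER137C beside SCR1 was at −8.36 (−8.64 to −8.11). COQ6, YIL102C, YJL028W and RPC17 were above 0 for TAP against ribo depletion but had too few counts to be measured here. The tRNA medians of the poly(A) libraries against ribo depletion thus cover different identifiers. SNX41 and NIP100, at 0 in ribo depletion, were at least 105.7-fold and 100.4-fold higher in CIP/TAP, with 256 and 243 counts. TCM62 had 0 counts in CIP/TAP as well, at least 1384-fold lower. In all, 619 of 1700 identifiers were at least 2-fold higher and 605 lower, and total counts moved the median by 1.05 and the higher share of the calls from 50.6% to 68.8%. A filter of 200 counts turned the balance to 270 higher and 461 lower.

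Both poly(A) comparisons used the same ribo depletion table. Among 1500 identifiers measured in both, 411 and 441 were higher in TAP and CIP/TAP, 350 in both. Independent lists would share 120.8 and libraries simulated from the ribo depletion counts alone 35.1. The simulations were scaled by total counts rather than TMM. An identifier at 0 in ribo depletion was simulated at 0 and so counted as higher in both. They therefore set no level of overlap to compare with for higher ratios. For lower ratios the numbers were 625, 604 and 535, against 251.7 and 3.15. The simulated 3.15 sets no level to compare with either, since lower calls depend on the scale. Over all measured identifiers, total counts gave 381 lower in TAP and 393 in CIP/TAP, where TMM gave 626 and 605. The log2 ratios had a Pearson correlation of 0.877 across identifiers and a covariance of 9.02. The 100 simulations, with the same limit, gave a correlation of 0.477 and a covariance of 0.0814. Part of the overlap beyond that of independent lists may come from the shared ribo depletion table, which could not be split. Across identifiers, which are not independent replicates, Spearman's rho of CPM was 0.78 between TAP and CIP/TAP, 0.51 between TAP and ribo depletion and 0.50 between CIP/TAP and ribo depletion, and Pearson's r of log2 CPM was 0.67, 0.42 and 0.41.

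The fixed gene lists, read by identifier, held few measured members. For H2A.Z and its remodellers the medians were 0.25 (13 of 26 measured) for CIP/TAP against TAP, 0.35 (12) for TAP against ribo depletion and 0.71 (10) for CIP/TAP against ribo depletion. ARP5 was at 2.21 (1.51 to 3.06) and ARP6 at −6.26 (−9.63 to −4.70) for CIP/TAP against TAP. Ribosome biogenesis genes were at 0.27 (10 of 35), 0.71 (12) and 0.80 (12) in the same order, with NOP58 at 3.27 (2.33 to 4.53) for TAP against ribo depletion. Proteasome genes were at 0.19 (11 of 31), 0.02 (12) and −1.01 (13), and these medians changed sign with upper-quartile scaling (−0.02), DESeq2 size factors (−0.10) and total counts (0.04). Ribosomal protein genes were at 3.13 (8 of 138), −5.26 (10) and −2.30 (13), and with genes listed at 0 set at their bounds at 2.20, −3.90 and −2.30. Glycolysis and fermentation genes were at 0.85 (3 of 21), −7.54 (5) and −6.21 (6), at their bounds 0.85, −4.95 and −4.91. The 95% interval spanned 0 for each of these medians with at least 6 measured members. With at least 200 counts, the ribosomal protein medians became 0.16 (3 members), −6.25 (4) and −6.01 (4), and those of the proteasome −0.10, −1.05 and −1.08 (5 members each). With 5 added to each count, ribosomal proteins were at 1.90 and −3.28 in the first pair of comparisons, and glycolysis and fermentation genes at −4.27 and −4.00 against ribo depletion. PGK1 had 240 counts in ribo depletion and 0 in both poly(A) libraries, and PFK2 was at −2.17 (−2.49 to −1.88) for TAP against ribo depletion.

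Substrates of nonsense-mediated decay were at 0.75 (4 of 11), −2.13 (3) and −0.86 (4, above 0 with total counts at 0.19), with PPR1 at −5.22 (−5.51 to −4.95) for TAP against ribo depletion. TCA cycle genes were at −0.61 (3 of 14) and 0.42 (4) in the first pair of comparisons, and respiratory chain genes at 1.02 (3 of 29) for CIP/TAP against TAP and 0.08 (4, or −0.04 with 5 added to each count) for CIP/TAP against ribo depletion. Ergosterol genes were at −4.34 (3 of 20) for CIP/TAP against ribo depletion. Every other list and comparison had under 3 measured members. Among these, translation factors, glucose-repressed genes and cell wall and membrane genes had 0. Core histones had HHT1 with 0, 24 and 36 counts, stress and heat shock genes had TPS2 with 21, 127 and 60, and cyclins and short-lived transcripts had CLB4 with 382, 1156 and 1220 and SIC1 with 19, 139 and 66. The noncoding, mitochondrial, tRNA, snoRNA and snRNA lists had no identifier in the tables.

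Divergent gene pairs were compared because the series title names the direction of transcription. An identifier's count is not described as the expression of that gene. The values below therefore compare counts listed under paired identifiers and do not show the direction of transcription. Among 533 of 1205 pairs with starts at most 1000 bp apart and both measured, Spearman's rho of CPM across pairs was 0.00, inside the range of random pairings (−0.09 to 0.08). The median absolute log2 difference was 1.94, and random pairings gave 1.94. With CPM per kb of gene length, rho was 0.18 (random −0.08 to 0.08) and the difference 1.91 (random 1.96 to 2.33), so the value depended on the unit. No relation is read from it, since 5′ ends were counted and gene length need not bear on them. The same identifier had the higher count in all 3 tables in 365 pairs (68.5%, 64.3 to 72.4%), a share close to that of convergent pairs (121 of 178, 68.0%, 60.6 to 74.8%). Among tandem pairs this held for 63 of 133 (47.4%, 38.7 to 56.2%). The extremes were ranked among 402 pairs with at least 200 summed counts in each table, by the smallest absolute log2 difference over the 3 tables. By that measure UTR5 and HYP2, JID1 and FCY1 (11334 against 2 counts in ribo depletion), and YLR358C and ADE13 (2815 against 0 in TAP) were the most unequal. EAF3 and YME1 (335 and 334 in TAP), YPT10 and TSC10 (315 and 317 in CIP/TAP), and MSC1 and RSC9 (328 and 331 in TAP) were the closest, each in the table named. The same pairs were unequal elsewhere. In ribo depletion EAF3 and YME1 had 336 and 1619 counts and MSC1 and RSC9 had 329 and 5937. In TAP YPT10 and TSC10 had 389 and 131. Tandem pairs gave −0.18 (133 pairs, random −0.17 to 0.17) and convergent pairs 0.01 (178 pairs, −0.14 to 0.15). The tandem value was inside the random range with a limit of 500 bp (−0.163, 98 pairs, −0.201 to 0.197) and with CPM per kb (−0.168, −0.171 to 0.169). Without ribosomal protein pairs it stayed just outside (−0.175, −0.171 to 0.172).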

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

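No paired analysis was possible because the replicate numbers shared by the immunoprecipitation and input samples had no values here, each poly(A) group was 1 library, and the 3 ribo depletion samples shared 1 table, so leaving out a replicate was not run either. Counts of identifiers at least 2-fold higher and lower stayed within 1.5 times under DESeq2 size factors, upper-quartile scaling, 5 added to each count, protein-coding nuclear genes only, thinning and, chosen after seeing the data, without DSC3. Filters change how many identifiers are measured. For CIP/TAP against TAP (373 higher, 262 lower), 10 counts gave 622 and 783, no filter 848 and 1115, and 200 counts 123 and 49, and exact intervals beyond 2-fold left 239 higher. For TAP against ribo depletion (525 and 626), 10 counts gave 1100 and 859, no filter 1486 and 1118, 200 counts 206 and 483, and total counts 850 and 381. For CIP/TAP against ribo depletion (619 and 605), 10 counts gave 960 and 876, no filter 1350 and 1183, 200 counts 270 and 461, and total counts 868 and 393. Keeping only identifiers with a divergent neighbour within 500 bp, also chosen after seeing the data, gave 185 and 148, 322 and 363, and 362 and 355 in that order, from fewer identifiers. Spearman's rho became 0.84 between TAP and CIP/TAP with 200 counts, 0.71 and 0.45 between TAP and ribo depletion with no filter and 200 counts, and 0.71 and 0.46 between CIP/TAP and ribo depletion. Pearson's r of log2 CPM with no filter and 200 counts was 0.85 and 0.86 between TAP and CIP/TAP. It was 0.77 and 0.39 between TAP and ribo depletion, and 0.79 and 0.38 between CIP/TAP and ribo depletion. Divergent pairs gave 0.18 with CPM per kb, and the cause was not tested. The median beside protein-coding genes changed sign for CIP/TAP against TAP with total counts (−0.0056) and upper-quartile scaling (−0.049). For TAP against ribo depletion (−0.09) it also changed sign, to 1.20 and 0.28 under these scalings, and for CIP/TAP against ribo depletion (0.03) it became 1.09 with total counts, by the same factor for every identifier. The medians beside tRNA genes (CIP/TAP against both others) and snoRNA and snRNA genes (all 3 comparisons) kept their sign under every scaling. Of 72 ratios of named genes, 47 moved beyond their counting interval with 5 added to each count and 0 with the other alternatives. Narrow intervals given elsewhere do not cover the choice of scaling. Total counts moved every ratio of TAP over ribo depletion by 1.28. The intervals of DSC3 (−8.43 to −8.26) and RRT15 (3.72 to 3.91) are narrower than that. Depth limits every identifier at 0 to a bound.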

Other observations

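Reading the fixed lists through the identifier opposite each gene was chosen after the values had been seen. Of 10 measured identifiers divergent to ribosome biogenesis genes, 6 were at least 2-fold higher in TAP than in ribo depletion and 2 lower. Their median was 1.04 (percentile 99.8 of random lists) with a 95% interval that spanned 0 (−1.05 to 2.70). In CIP/TAP 5 were higher and 1 lower, with a median of 0.93 (−0.30 to 2.17). SEC62 opposite NOG1 was at 2.99 (2.56 to 3.46), MDM20 opposite BRX1 at 2.70 (2.24 to 3.22), TSC13 opposite NOP1, the fibrillarin gene, at 2.04 (1.92 to 2.17), and GEP3 opposite NOC2 at −2.37 (−2.47 to −2.27). Of 10 measured identifiers opposite proteasome genes, 6 were lower in TAP and 1 higher. The median of −2.11 had an interval that spanned 0 (−3.59 to 0.98) and lay at percentile 6.40 of random lists, and in CIP/TAP it was −1.85 (−2.98 to 1.09). GCD1 opposite RPT4 was at −3.69 (−3.78 to −3.60) and MPO1 opposite SCL1 at 1.10 (0.89 to 1.32). Against ribo depletion the medians of both lists kept their sign under all 4 scalings. Other lists of protein-coding genes with at least 3 measured members were H2A.Z and its remodellers at −0.33 in TAP (8 measured, percentile 28.7) and −0.66 in CIP/TAP (7, percentile 26.3), both above 0 with total counts (0.95 and 0.40) and the first also with upper-quartile scaling (0.03), substrates of nonsense-mediated decay at 0.52 (4) and 0.23 (3), and ribosomal proteins at 0.24 (3) and 0.35 (4). The respiratory chain had 3 measured in CIP/TAP, all higher (5.24, percentile 99.5), and 2 in TAP. For CIP/TAP against TAP the medians ran from −0.62 for substrates of nonsense-mediated decay to 0.81 for the respiratory chain. Each remaining list of protein-coding genes had under 3 measured.

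Some identifiers whose nearest upstream gene was tandem had counts too. Only the nearest gene was classed, so a divergent gene farther upstream or overlapping it was not looked for. These identifiers are thus not shown to lack a close divergent gene. Of 2794 with a tandem neighbour, 628 had at least 10 counts in TAP, 508 in CIP/TAP and 297 in both, where independent detection would give 114.2. Detection in all 3 tables was found for 172, where independent detection would give 19.6. The highest in TAP, named after their values were seen, were RRT15, TIP41 (3208, 3855 and 4708 counts in ribo depletion, TAP and CIP/TAP), RTN2 (6683, 3389 and 5245), KRR1 (2807, 2607 and 3829) and YGR026W (1667, 1675 and 1580).

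The tests below were chosen after the patterns were seen. Those on neighbours over 500 bp away were set before their values were computed.

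Counts lay on identifiers beside divergent neighbours, and no biological explanation was tested. Own-strand reads that take in the 5′ end of each gene are argued against for ribosomal protein genes, since 7.25% of them had at least 10 TAP counts. The counted feature is not given. Own-strand counting that leaves out the 5′ ends, or drops reads shared between gene copies, is therefore not excluded. Opposite-strand reads over the gene body were taken to give the same share for divergent and tandem neighbours at the same gap, since neither crosses the body. The shares differed by 67.5 percentage points in TAP. That difference is the pattern that prompted the explanations, so it is no independent test of this one. A candidate explanation, found from the 87.4% for divergent neighbours against 19.9% for tandem ones and so not tested by them, is that reads on the opposite strand in a window upstream of each gene were counted, by choice or by setting. Its test asked for higher counts opposite the ribosomal protein, glycolysis and translation factor lists at 150 to 350 bp, leaving out UTR5 and YHR173C. The median TAP count there was 1665, against 151 (131 to 166) opposite other protein-coding genes, but with 2 identifiers no interval can be had and the explanation stays open. Under that hypothesis the DSC3 count would be of SNR35 5′ ends and the YHR173C count of ENO2 5′ ends.

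Of 8 identifiers beside tRNA genes 7 were low in CIP/TAP, as was the 1 beside SCR1. Scaling is argued against, since it moves every ratio alike, and 8 of these 9 (88.9%, 51.8 to 99.7%) lay at least 2-fold below the median of identifiers beside protein-coding genes, as did 15.1% (13.0 to 17.4%) of the latter. The pattern was seen in these same 9 identifiers, so the shares bear on a common scale only and add no support to the pattern. Reads shared between gene copies are argued against for SCR1, the only annotated gene of its kind, at −5.32, but for the 299 annotated tRNA genes copies cannot be told apart without their sequences. The hypothesis that CIP removed the 5′ phosphates of uncapped polymerase III transcripts stays open. Its test asked that identifiers whose divergent tRNA gene lay over 500 bp away not be low, and the median of 24 was −0.12, but any cause acting through a close neighbour would give the same. PMT7 went the other way, and 1 library of each kind leaves differences between preparations open.

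Identifiers beside snoRNA and snRNA genes were low in both poly(A) libraries. A scale set by DSC3 is argued against, since it would move every ratio alike. Without DSC3, 8 of 11 (72.7%, 39.0 to 94.0%) lay at least 2-fold below the median of identifiers beside protein-coding genes in each library, as did 31.7% (28.9 to 34.7%) of the latter in TAP and 33.0% (30.2 to 36.0%) in CIP/TAP. The deeper ribo depletion table is argued against, since after thinning the shares were 75% (9 of 12, 42.8 to 94.5%) in each library against 32.0% (29.2 to 35.0%) and 32.8% (29.9 to 35.7%). The pattern was seen in these same identifiers, so the shares bear on scale and depth only and add no support to the pattern. The hypothesis that the low ratios come from a missing poly(A) tail on these RNAs stays open. Its test asked that identifiers over 500 bp from such a gene not be low. They were, at a median of −7.76, or −5.17 with the 3 at 0 in TAP set at their bounds. These were 4, under the minimum of 5 set for it, and a missing tail sets no distance. Identifiers beside tRNA genes, whose RNA also lacks a tail, went both ways in TAP (median −0.15, 1.13 with total counts and 0.21 with upper-quartile scaling) and were low in CIP/TAP (−6.85, 6 of 7 lower), and the identifier beside SCR1 was low in both (−3.11 and −8.36). Selection and preparation, enzyme treatment included, cannot be told apart with 1 table of each kind.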
